A study of Homo sapiens with 6 samples.

How the data were processed

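Human monocytes positive for CD14 and CD16 had been isolated from peripheral blood mononuclear cells and kept for 7 days in 20 ng/ml M-CSF, the growth factor that drives macrophage differentiation. The resulting macrophages then received either 100 nM of the protein ADA2 (adenosine deaminase 2) or phosphate-buffered saline (PBS) for 48 hours. Polyadenylated RNA was sequenced in pairs on an Illumina HiSeq, per the labels' protocols. The 6 libraries fall into 2 groups of 3, ADA2 and PBS, named by group and replicate number as in the sample titles. The labels do not say whether replicates of a group come from separate donors or separate cultures, so the p-values given here measure only the spread between these libraries, which may be technical.

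Per the submitters' processing notes, the authors used Trimmomatic 0.36, STAR 2.5.2b and DESeq2 with the genome build GRCh38. The read counter, its settings and the annotation release are not given in the sources used here. The deposited counts are whole numbers per exon bin and per library, in 597973 bins per library, per the file headers and the values: each gene is cut into non-overlapping pieces of its exons, and overlapping genes of the same strand are joined into 1 feature. A read was counted in every bin it touched. Sums over a gene's bins exceeded the authors' gene level by a median of 2.589 times over 12009 genes, from 1.097 times in genes of 1 bin to 3.417 times in genes of over 40 bins. Counting took no account of strand: all 15 pairs of bins at the same coordinates on opposite strands that held counts had equal totals. The authors also deposited a table of rlog values, log2 expression per gene and library shrunken towards the mean of each gene, for 15470 genes. That table served only for an alternative test and for the over-count ratios above.

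Bins were summed to genes. Bins of a joined feature were given to a gene where the exons of GENCODE release 29 (GRCh38) placed them in that gene alone, and bins given to no single gene, which held 3.58% of the counts, stayed out of the sums. Bins overlapped by an exon of the opposite strand, with 8.88% of the counts, were left out as well, and 87.54% of the counts were kept. The sums cover 54840 genes, of which 54446 had a symbol. Gene positions are those of the same annotation. JUNB, 1 of the genes listed in advance, had no bin free of opposite-strand overlap and was not analysed here. Because a read can count in several bins, the gene sums are larger than the number of reads, counts within a gene are not independent, and a long gene with many short exons weighs more. Levels are gene sums as CPM after TMM scaling, and compare libraries rather than genes.

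The total of bin counts was 145100477, 149214145 and 116362545 in ADA2 replicates 1, 2 and 3, and 142714203, 130713372 and 162853664 in PBS replicates 1, 2 and 3. A group without a count was set to a floor of 3 counts over its libraries, and its fold was computed from the gene's largest bin, in which a read counts once. For groups with 1 to 3 summed counts the ratio of largest-bin counts is given with its exact Clopper-Pearson 95% interval. Reads carried no molecular identifiers, so intervals and floors cover counting error only.

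The design, the gene lists and the alternatives were fixed before the data were examined, except where stated. Groups were compared with edgeR 4.0.16 in R 4.3.3: filterByExpr kept 16127 genes, TMM scaled the libraries, and the quasi-likelihood F test without a covariate gave two-sided p-values with Benjamini-Hochberg adjustment at 0.05. Standard errors of log2 fold changes are the fold change over the square root of F. The 36 gene lists were tested with camera (limma 3.58.1, voom values, preset inter-gene correlation of 0.01, Benjamini-Hochberg over lists with at least 5 tested genes). They hold 24 response lists, 10 lists of cell type markers and 2 lists on RNA quality. Listed symbols were matched through current and older names. Shares of library composition were compared by a two-sided exact permutation test, which for 3 against 3 cannot go below 0.1. Coverage along genes was described by the log2 ratio of counts at the 5' end to those at the 3' end, each end being 1 of 3 equal parts of a gene's bins, over 3391 protein-coding genes with at least 9 bins and at least 2000 counts in each library.

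Genes named in the text were chosen by a rule written in advance. It takes ADA2, ADA and the adenosine receptors, then the 14 largest rises and 14 largest falls among called genes with a mean of at least 5 CPM in the higher group. It adds up to 4 members of each response list with the smallest p, and the 2 most abundant members of each marker or RNA quality list. Some genes that the rule takes are not reported here. Other names are marked as chosen after their values were seen.

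The alternatives were DESeq2 size factors, library totals without composition scaling, no low-count filter, a stricter filter, the DESeq2 1.42.0 Wald test, limma-voom, the replicate number as a block, limma on the deposited rlog values, other thresholds, and each library left out in turn. For lists they were an estimated correlation, the self-contained test fry, the block and DESeq2 size factors. Added after the data were seen were the largest bin of each gene, opposite-strand bins kept, bins of the 3' end part alone, library totals for lists, and families of genes that share a symbol stem.

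The test was tried on simulated counts drawn from the PBS means, the library sizes and the fitted dispersion of this comparison, with 200 of the genes changed. With each read counted once, 48% of 50 genes changed 1.5-fold, 78% of 50 changed 2-fold, 98% of 50 changed 4-fold and 100% of 50 changed 8-fold were called, and 3.6% of 168 calls were false. With each read counted in 3 bins these shares were 30%, 74%, 92% and 100%, and 3.9% of 154 calls were false. Of 36 simulated lists of 20 genes over 16127 genes, all 4 lists changed 2-fold were called and 0 of 32 unchanged lists were. Simulated genes varied independently, so the list trial cannot show how camera behaves where genes are correlated. The changed genes were few, balanced between rises and falls and not of the lowest levels. In the data 70.9% of tested genes were called, so these shares need not hold there. A log2 shift of -1.0 put into the 5' end part of bins in 3391 genes was measured as -1.0. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used for the summing and the composition.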

Results

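Messenger RNA was compared between human monocyte-derived macrophages that had received ADA2 protein for 48 hours and macrophages that had received PBS, with 3 libraries in each group. ADA2 is a secreted enzyme of blood that deaminates adenosine, and the series asks how it affects human macrophages. Totals of exon-bin counts lay between 116362545 and 162853664 per library. Levels below are CPM of gene sums after TMM scaling, as mean ± SD over n = 3 libraries, and folds are ADA2 over PBS.

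The transcriptome of macrophages given ADA2 differed widely from that of macrophages given PBS. Of 16127 genes tested, 5569 were higher and 5860 lower in ADA2, and 4698 were not called by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p of 0.05. Camera called lists of NF-kB cytokines, inflammatory chemokines, matrix metalloproteinases, glycolytic and hypoxia-induced genes and metallothioneins higher, and 0 lists passed it higher with an estimated correlation (7 at an unadjusted p under 0.05). Lists of cell cycle genes, mitochondrially encoded mRNAs and markers of differentiated macrophages were called lower, and 0 passed camera lower with an estimated correlation, also 0 at an unadjusted p under 0.05. At least 2-fold changes were seen for 3661 of the higher and 3481 of the lower genes. The fitted change was at least 8-fold for 1154 genes that rose and 524 that fell. Of these, 177 had at most 3 summed counts in PBS and 99 at most 3 in ADA2, so their fitted folds are imprecise. Every gene said below to have risen or fallen passed that test. Among the genes named by rule, the edgeR quasi-likelihood Benjamini-Hochberg adjusted p ran from 4.0e-09 to 0.025. TMM placed the median gene at a log2 fold change of -0.04, and library totals without such scaling placed it at -0.64. With library totals 3476 genes were higher and 8889 lower, so that 28.1% of calls were rises instead of 48.7%.

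CXCL8 (interleukin 8, a neutrophil attractant; ENSG00000169429, chromosome 4, 73740506 to 73743716, plus strand, GRCh38) rose from 22.9 ± 2.02 to 46100 ± 6270 CPM, a log2 fold change of 10.97 ± 0.17 (SE). IL1B, which encodes the inflammatory cytokine interleukin 1 beta (chromosome 2, 112829751 to 112836903, minus strand), rose from 6.94 ± 1.37 to 16000 ± 1570 CPM, a log2 fold change of 11.17 ± 0.22 (SE). CXCL8 alone made up 3.73% of gene sums in ADA2 and 0.00283% in PBS. Among the 14 largest rises, CSF3, the granulocyte growth factor, rose from 0.564 ± 0.148 to 2580 ± 246 CPM. CSF2, the granulocyte and macrophage growth factor, rose from 0.0963 ± 0.0756 to 457 ± 33.5 CPM. Levels of IL23A, a subunit of interleukin 23, rose from 0.644 ± 0.0941 to 2190 ± 276 CPM, and the chemokines CXCL2 and CCL20 reached 3170 ± 275 and 1160 ± 201 CPM from 1.1 ± 0.111 and 0.278 ± 0.101 CPM. The stromelysin gene MMP3 rose from 0.0448 ± 0.04 to 251 ± 11.3 CPM, and DLL4, a Notch ligand, from 0.0219 ± 0.0202 to 76.8 ± 10.5 CPM. In PBS the largest bin of MMP3 held 1 count and that of DLL4 held 3, so the sizes of these rises are imprecise. Without PBS replicate 3 the log2 fold change was 13.02 instead of 12.14 for CSF2 and 12.36 instead of 11.63 for DLL4, and without PBS replicate 1 it was 11.85 instead of 12.44 for MMP3.

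Several of the strongest rises started from almost no counts. SERPINB4, a serpin with a near-identical neighbour, and C2CD4A had 0 counts in PBS and were at least 318-fold and at least 874-fold higher in ADA2. MT1B, a metallothionein, was at least 664-fold higher, but its ADA2 libraries held 2.49, 6.13 and 20.8 CPM, and its reads can be shared with other metallothionein genes. IL36G, IL12B, IL11 and C2CD4B each had 1 count in the largest bin in PBS. The ratio of largest-bin counts was 10400 for IL36G (95% interval 1870 to 412000), 3320 for IL12B (596 to 131000), 2440 for IL11 (438 to 96600) and 4300 for C2CD4B (771 to 170000). Their ADA2 levels were 66.6 ± 7.79, 18.5 ± 5.18, 18.3 ± 5.75 and 11.1 ± 2.3 CPM. The fitted log2 fold change of IL36G was 13.15, or 15.97 without PBS replicate 1 and 12.54 without PBS replicate 3. Those of IL12B, IL11 and C2CD4B were 14.08, 14.07 and 13.34 without PBS replicate 3, instead of 12.54, 12.53 and 11.81.

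**Figure D1:**
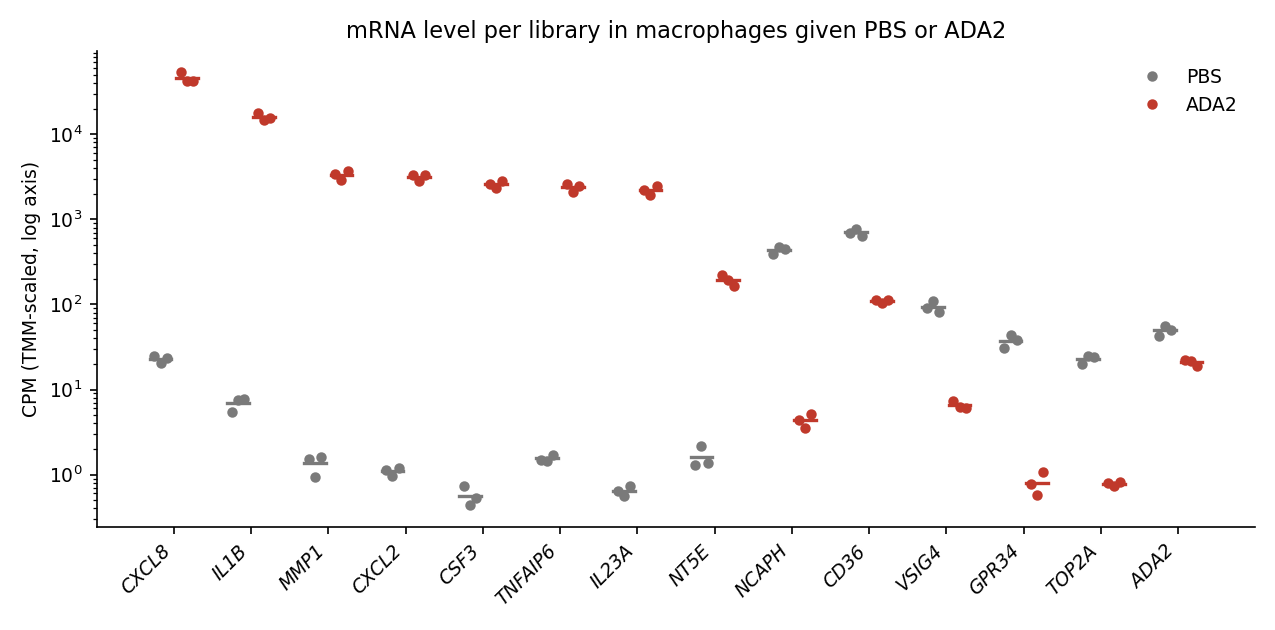
CPM per library (points, log axis) and group mean (bars) for 14 genes in macrophages given PBS (grey) or ADA2 (red), 3 libraries each. CXCL8 lies at 46100 CPM in ADA2 against 22.9 in PBS, and NCAPH at 4.33 against 439.

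Among the 14 largest falls, NCAPH, a condensin subunit that packs chromosomes in mitosis (chromosome 2, 96335787 to 96373845, plus strand), fell from 439 ± 41.2 to 4.33 ± 0.79 CPM, a log2 fold change of -6.67 ± 0.17 (SE). BIRC5, the mitotic protein survivin, fell from 7.08 ± 0.281 to 0.0776 ± 0.0595 CPM. The monocyte attractant CCL2 fell from 29.5 ± 9.14 to 0.306 ± 0.293 CPM. The receptor genes LILRB5 and GPR34 fell from 19.4 ± 6.85 and 37.5 ± 6.78 to 0.352 ± 0.11 and 0.803 ± 0.246 CPM, and MS4A6A from 23 ± 9.52 to 0.433 ± 0.186 CPM. Actin-linked WIPF3 fell from 8.92 ± 1.81 to 0.0536 ± 0.0391 CPM. The transcription factor HHEX fell 56-fold, the lysosomal nuclease DNASE2B 54.1-fold, FAIM2 82.6-fold, TMEM37 70.2-fold and FCGBP 46.9-fold. The potassium channel KCNMA1 fell from 6.12 ± 0.298 to 0.109 ± 0.0998 CPM, a log2 fold change of -5.75, or -6.70 without ADA2 replicate 1. For CCL2 the log2 fold change was -6.58, or -7.77 without ADA2 replicate 1, and for BIRC5 -6.58, or -7.31 without ADA2 replicate 3.

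**Figure D2:**
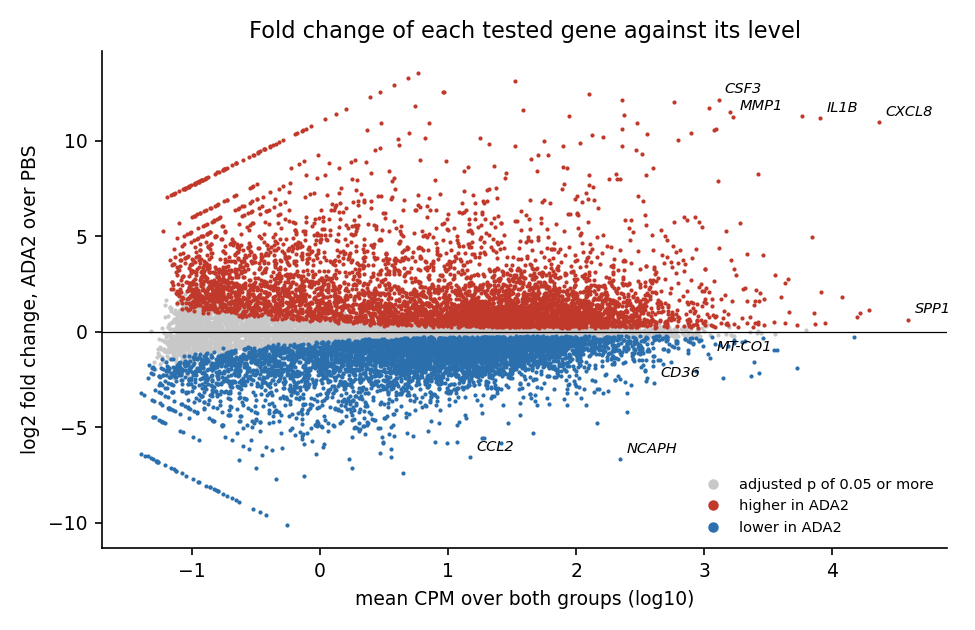
Fitted log2 fold change (ADA2 over PBS) against mean CPM (log10) for the tested genes, with the 5569 higher genes in red, the 5860 lower genes in blue and the rest in grey. Points on straight diagonals are genes with 0 or very few counts in a group, whose fitted value is not a bound.

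Genes of purine and adenosine biology moved in both directions. ADA2 mRNA itself (chromosome 22, 17178790 to 17258235, minus strand) fell 2.34-fold, from 49.6 ± 6.65 to 21.2 ± 1.8 CPM, a log2 fold change of -1.23 ± 0.12 (SE). ADA, the intracellular deaminase, rose 6.86-fold from 8.09 ± 1.33 to 55.4 ± 5.32 CPM. Of the 4 adenosine receptors, ADORA2A and ADORA2B rose and ADORA1 and ADORA3 fell. ADORA2A had 1 count in its largest bin in PBS and 14.1 ± 2.2 CPM in ADA2, a ratio of largest-bin counts of 4260 (95% interval 763 to 168000), and ADORA2B rose from 0.804 ± 0.0522 to 8.28 ± 0.793 CPM. ADORA1 fell from 0.61 ± 0.0197 to 0.0251 ± 0.00998 CPM and ADORA3 from 1.84 ± 1.01 to 0.0225 ± 0.0246 CPM. The largest bin of ADORA1 held 84 counts in PBS and 0 in ADA2, so the size of its fall is imprecise. The fitted log2 fold change of ADORA2A was 10.92, or 13.69 without PBS replicate 3. The log2 fold change of ADORA3 was -6.39, or -5.79 without ADA2 replicate 1 and -7.43 without ADA2 replicate 3. ADORA2A and ADORA3 each lie in a feature joined with a neighbouring gene, which makes their values less certain. NT5E (CD73), which makes adenosine from AMP, rose 122-fold to 194 ± 27.5 CPM, and the adenylate kinase AK4 10.3-fold to 356 ± 38.1 CPM. In the purine list as a whole 11 of 28 genes rose and 13 fell, also 11 and 13 adjusted over the list alone, and camera called no direction (Benjamini-Hochberg adjusted p = 0.94).

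All 27 tested members of the list of NF-kB cytokines and mediators rose, also 27 adjusted over the list alone, with a median log2 fold change of 5.31. Camera called the list higher (Benjamini-Hochberg adjusted p = 8.6e-15), with adjusted p = 0.18 with an estimated correlation. Besides IL1B, IL23A and IL12B, the hyaluronan-binding TNFAIP6 rose from 1.55 ± 0.152 to 2380 ± 259 CPM and the adaptor TRAF1 from 9.17 ± 0.272 to 530 ± 40.1 CPM. Of 19 inflammatory chemokines 16 rose and 3 fell, the same numbers adjusted over the list alone. Those that fell were the monocyte attractants CCL2 and, chosen after their values were seen, CCL7 and CCL8, at log2 fold changes of -6.58, -4.06 and -1.62. Camera called the chemokine list higher (Benjamini-Hochberg adjusted p = 3.5e-06), with adjusted p = 0.24 with an estimated correlation. CCL3L3 rose from 26 ± 3.34 to 1670 ± 189 CPM, with reads it can share with CCL3.

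Interferon-related genes did not move as a block. Of 18 tested genes on the list of interferon gamma responses, 15 rose and 2 fell, the same adjusted over the list alone, and camera called the list higher (Benjamini-Hochberg adjusted p = 5.5e-05; adjusted p = 0.25 with an estimated correlation). CXCL9, the only chemokine tested on that list and chosen after its value was seen, did not pass, at 0.186 ± 0.0484 CPM in ADA2. IDO1, which degrades tryptophan, rose from 0.296 ± 0.157 to 453 ± 33.9 CPM. The cytokine IL32 rose 55-fold and the transcription factor IRF1 17.1-fold, while the Fc receptor FCGR1A fell from 16.3 ± 1.19 to 0.604 ± 0.194 CPM. Among 35 type I interferon response genes 13 rose and 13 fell, also 13 and 13 adjusted over the list alone, and camera gave no call (Benjamini-Hochberg adjusted p = 0.94). In that list the antiviral RSAD2 and its neighbour CMPK2 rose 74.6-fold and 25.8-fold, and PARP9 and TRIM22 fell 3.99-fold and 4.52-fold. The list of MHC class II antigen presentation also holds costimulators. In it 6 of 16 genes were higher and 8 lower, the same adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.94). The 8 that fell, named after their values were seen, were all genes of the class II pathway. HLA-DMB, CIITA (the class II transactivator), HLA-DOA and HLA-DMA fell at log2 fold changes of -2.31, -2.15, -2.04 and -1.91. HLA-DPA1, HLA-DPB1, HLA-DRA and CD74 fell at -1.18, -1.01, -0.61 and -0.5. Of the 6 that rose, CD80, CD40 and CD86 are costimulators, which rose 56.6-fold, 4.37-fold and 2.33-fold. The others that rose were class II genes. HLA-DQA1 rose 9.05-fold. HLA-DRB5 and HLA-DRB1, named after their values were seen, rose at log2 fold changes of 0.98 and 0.42. For HLA-DRB1 the edgeR quasi-likelihood Benjamini-Hochberg adjusted p was 0.046. HLA-DQB1, chosen after its value was seen, did not pass, at a log2 fold change of 0.11. For CD80, 24.1% of counts lay in bins overlapped on the opposite strand and were left out.

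Matrix-degrading enzymes and their inhibitors rose: 21 of 23 were higher and 0 lower, the same adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 7.3e-08; adjusted p = 0.16 with an estimated correlation). The collagenase MMP1 (chromosome 11, 102789920 to 102798160, minus strand) rose from 1.35 ± 0.365 to 3340 ± 379 CPM, matrilysin MMP7 from 245 ± 6.79 to 4070 ± 475 CPM, the inhibitor SERPINB2 from 0.298 ± 0.0759 to 597 ± 38.9 CPM and ADAM8 4.29-fold. Of 24 growth factors and receptors 18 rose and 4 fell, the same adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 2.0e-05; adjusted p = 0.25 with an estimated correlation). INHBA, the activin A subunit, rose from 1.14 ± 0.202 to 1580 ± 104 CPM, and BMP6 and oncostatin M (OSM) rose 108-fold and 73.2-fold. In the list of extracellular matrix and adhesion genes 12 of 22 rose and 8 fell (13 and 8 adjusted over the list alone), without a call by camera (Benjamini-Hochberg adjusted p = 0.52). The integrins ITGB8 and ITGA5 rose 304-fold and 7.71-fold, laminin LAMB3 rose 21.8-fold, and the integrin ITGA3 fell 9.34-fold.

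Glycolytic enzymes, glucose transporters and other targets of hypoxia signalling rose in all 29 tested members, also 29 adjusted over the list alone, with a median log2 fold change of 3.29. Camera gave a Benjamini-Hochberg adjusted p = 2.8e-15, and adjusted p = 0.18 with an estimated correlation. The carbonic anhydrase CA12 rose from 0.21 ± 0.0192 to 264 ± 29.1 CPM, the vasodilator peptide ADM from 10.8 ± 1.17 to 2540 ± 350 CPM, the enolase ENO2 from 35.3 ± 3.31 to 979 ± 27.8 CPM and EGLN3, a prolyl hydroxylase that targets HIF, 211-fold. Oxidative phosphorylation genes of the nucleus shifted modestly, with 2 of 31 higher and 18 lower, the same adjusted over the list alone, and a median of -0.31 (camera, Benjamini-Hochberg adjusted p = 0.016; adjusted p = 0.73 with an estimated correlation). The ATP synthase subunits ATP5PB and ATP5F1A fell 2.18-fold and 2.16-fold, NDUFS1 of complex I 2.13-fold and SDHC of complex II 1.84-fold. Mitochondrially encoded mRNAs fell further: all 13 were lower, also 13 adjusted over the list alone, with a median of -2.74 (camera, Benjamini-Hochberg adjusted p = 1.6e-06; adjusted p = 0.34 with an estimated correlation). MT-CO1 fell from 1600 ± 194 to 624 ± 54.3 CPM and MT-ND4 from 733 ± 125 to 223 ± 24.8 CPM. Cytosolic ribosomal protein mRNAs, the other list kept as a sign of RNA quality, had 2 of 32 members higher and 8 lower (1 and 7 adjusted over the list alone) and no call by camera (Benjamini-Hochberg adjusted p = 0.44). RPLP0 stood at 1830 ± 127 in PBS and 1570 ± 107 CPM in ADA2, and RPL8 at 982 ± 60.9 and 998 ± 31 CPM; neither passed the test. Under library totals camera called the ribosomal protein list lower, at a median of -0.67 (Benjamini-Hochberg adjusted p = 0.0013), against adjusted p = 0.97 with an estimated correlation under TMM. Library totals also called RPLP0 and RPL8 lower, at -0.83 and -0.58. RPLP0 was also called lower without a filter (-0.30) and by limma-voom (-0.22).

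Cell cycle genes fell in 29 of 30 cases (30 adjusted over the list alone), with a median of -2.92 (camera, Benjamini-Hochberg adjusted p = 8.4e-10; adjusted p = 0.28 with an estimated correlation). The topoisomerase TOP2A (chromosome 17, 40388516 to 40417950, minus strand) fell 29.1-fold, from 22.8 ± 2.73 to 0.785 ± 0.045 CPM. The kinetochore gene CENPF fell 19.6-fold, the spindle factor TPX2 14.6-fold and the cyclin CCNA2 12.8-fold; 35.4% of CCNA2 counts lay in opposite-strand bins that were left out. Levels of these genes in PBS were low, at most 22.8 CPM for the 4 named.

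All 10 members of the metallothionein list rose, also 10 adjusted over the list alone, at a median of 5.72 (camera, Benjamini-Hochberg adjusted p = 1.8e-05; adjusted p = 0.34 with an estimated correlation). MT2A rose from 75 ± 2.33 to 2870 ± 905 CPM, MT1G from 70.4 ± 20.2 to 3720 ± 1260 CPM, MT1E 33.1-fold and MT1X 53.6-fold; these paralogs can share reads. In the list of amino acid and unfolded protein stress 20 of 25 genes rose and 4 fell, the same adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 7.1e-06; adjusted p = 0.19 with an estimated correlation). The 4 that fell, HYOU1, PDIA4, CRELD2 and SDF2L1, named after their values were seen, are genes of protein folding in the endoplasmic reticulum, at log2 fold changes from -0.83 to -1.77. SESN2 rose 24-fold, the amino acid transporter SLC7A5 20.3-fold, the phosphatase subunit PPP1R15A 14-fold and DDIT4 90.7-fold, with 55.9% of DDIT4 counts left out for opposite-strand overlap. The cAMP and CREB list had 17 of 19 genes higher and 1 lower, the same adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 4.2e-07; adjusted p = 0.16 with an estimated correlation). In it the phosphatase DUSP1 rose 114-fold, the lipolysis inhibitor G0S2 379-fold, the phosphodiesterase PDE4B 191-fold and the nuclear receptor NR4A3 10.2-fold.

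Of 14 heat shock genes 3 rose and 8 fell, the same adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.13), and without ADA2 replicate 3 the list was called lower by camera (Benjamini-Hochberg adjusted p = 0.041), at a median of -0.85 against -0.73. Library totals called it lower too (camera, Benjamini-Hochberg adjusted p = 0.048), and TMM with an estimated correlation did not (adjusted p = 0.43 with an estimated correlation). The chaperones HSPA8, HSPD1, HSPH1 and HSP90AB1 fell 5.32-fold, 2.65-fold, 2.62-fold and 2.4-fold. The NRF2 list held 10 higher and 4 lower of 19, the same adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.09); heme oxygenase HMOX1, thioredoxin TXN, AKR1B1 and the glutathione synthesis gene GCLM rose 6.79-fold, 6.5-fold, 6.36-fold and 4.22-fold. In that list ME1 and OSGIN1, chosen after their values were seen, fell, at log2 fold changes of -1.58 and -1.48.

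Lipid genes were divided. Cholesterol biosynthesis had 12 of 24 genes higher and 7 lower, LXR targets 9 of 15 and 4, and PPARG targets and lipid handling 7 of 16 and 7, the same numbers adjusted over each list alone; camera called none of them (Benjamini-Hochberg adjusted p = 0.55, 0.17 and 0.94). LSS and INSIG1 rose 3.06-fold and 2.8-fold, whereas ACAT2 fell 4.15-fold and TMEM97 fell 7.53-fold, with 25.6% of TMEM97 counts left out for opposite-strand overlap. The cholesterol exporter ABCG1 rose 19.4-fold and the desaturase SCD 6.38-fold, and NR1H3, which encodes LXR alpha, fell 2.79-fold. Lipid droplet genes HILPDA and PLIN2 rose 255-fold and 11.6-fold, ANGPTL4, an inhibitor of lipoprotein lipase, rose from 0.272 ± 0.0849 to 322 ± 23.4 CPM, and the fatty acid receptor CD36 (chromosome 7, 80369575 to 80679277, plus strand) fell from 700 ± 60.6 to 110 ± 5.34 CPM.

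Genes of alternative activation included 7 of 26 higher and 15 lower (8 and 15 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.17). The complement receptor VSIG4 fell 14.3-fold and the selenium carrier SELENOP 39.6-fold, the latter from bins holding the small part of its counts free of opposite-strand overlap, since 78.7% were left out. The chemokines CCL18 and CCL17 of the same list rose 51.2-fold and 35-fold. Among lysosomal genes 19 of 34 rose and 5 fell, among complement genes 9 of 18 and 7, and among pattern recognition and Fc receptors 11 of 27 and 12, the same numbers adjusted over each list alone; camera called none (Benjamini-Hochberg adjusted p = 0.17, 0.52 and 0.94). The protease CTSL rose 4.88-fold, the cholesterol transporter NPC1 4.85-fold and the proton pump subunit ATP6V0D2 1.94-fold, with 34.2% of its counts left out, and TFEB, a regulator of lysosome genes, fell 3.03-fold. Complement C3 and CFB rose 15.2-fold and 63.7-fold, C1S 9.95-fold and SERPING1 19.8-fold, whereas C1QC, CR1, C1QA and C1QB, chosen after their values were seen, fell, at log2 fold changes of -2.45, -2.34, -1.78 and -1.40. The receptors NOD2, TREM1 and CLEC4E rose 28.6-fold, 25.9-fold and 4.91-fold, with 28.1% of NOD2 counts left out. FCGR1A of the same list fell 27.2-fold, and TLR7, TLR5, TREM2 and TLR4, chosen after their values were seen, fell, at log2 fold changes of -4.85, -3.29, -2.78 and -1.27. Under library totals the medians of the lysosome, complement, cholesterol, matrix and adhesion, NRF2 and purine lists turned from above 0 to -0.27, -0.26, -0.43, -0.05, -0.03 and -0.54.

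**Figure D3:**
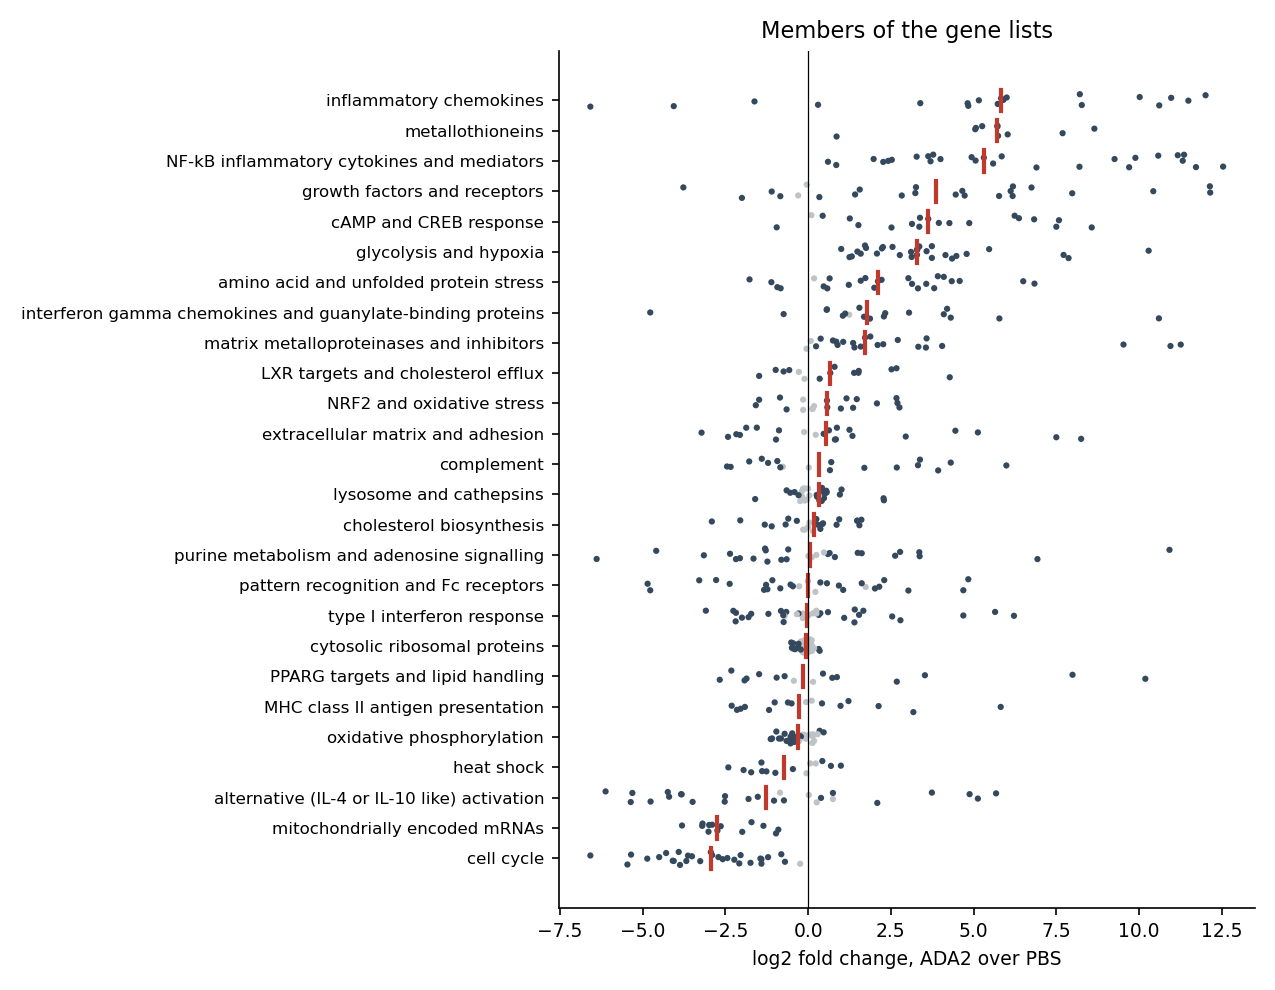
Log2 fold change (ADA2 over PBS) of each tested member of the 24 response lists and the 2 RNA quality lists; dark points passed the edgeR test, light points did not, and red bars are list medians. Medians run from -2.92 for cell cycle to 5.83 for inflammatory chemokines.

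Most markers of differentiated macrophages fell, and markers of other cell types moved in both directions. Of 17 macrophage markers 1 rose and 13 fell, the same adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 5.5e-04; adjusted p = 0.25 with an estimated correlation). GPNMB fell 1.96-fold from 4920 ± 130 to 2520 ± 375 CPM, and APOE stood at 3700 ± 273 in PBS and 3430 ± 662 CPM in ADA2, which did not pass. APOE was called lower without ADA2 replicate 3 (log2 fold change of -0.27) and under library totals (-0.71). Of 12 monocyte markers 5 rose and 3 fell; the coreceptor CD14 fell 1.38-fold, and LYZ stood at 634 ± 29.5 and 566 ± 114 CPM without passing, with 50% of its counts left out; library totals called LYZ lower (-0.77). Among 10 dendritic cell markers 4 rose and 5 fell, with CCR7, the lymph node homing receptor, rising from 0.551 ± 0.157 to 711 ± 90 CPM and LAMP3 from 0.177 ± 0.0312 to 56.8 ± 6.61 CPM. CD1A and CD1C of that list, chosen after their values were seen, fell, at log2 fold changes of -2.47 and -2.53. The counts for these monocyte and dendritic lists were the same adjusted over each list alone, and camera called neither (Benjamini-Hochberg adjusted p = 0.94 for both).

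NK cell markers were called higher by camera, with 5 of 7 higher, also 5 adjusted over the list alone (Benjamini-Hochberg adjusted p = 0.0096; adjusted p = 0.25 with an estimated correlation). That call was lost without ADA2 replicate 3 (Benjamini-Hochberg adjusted p = 0.085) and without PBS replicate 1 (0.054), where 8 and 9 members were tested, with 5 higher and 1 lower in each case and medians of 2.61 and 2.04 against 3.19. NCAM1 rose from 1.62 ± 0.154 to 19.3 ± 2.32 CPM and GZMB from 0.689 ± 0.099 to 6.28 ± 0.781 CPM. For T cells 4 of 8 rose and 1 fell, for B cells 3 of 7 and 1, for platelets 4 of 5 and 1, for neutrophils 3 of 7 and 2, for red cells 3 of 6 and 1, and for fibroblasts and endothelium 2 of 9 and 5. Those numbers were the same adjusted over each list alone, and camera called none of the lists (Benjamini-Hochberg adjusted p from 0.13 to 0.5). Under library totals camera called the platelet list higher, at a median of 1.86 (Benjamini-Hochberg adjusted p = 0.021), against adjusted p = 0.34 with an estimated correlation under TMM. FCRLA reached 17.2 ± 4.28 CPM and GP1BA 5.43 ± 0.639 CPM, and the chemokine PPBP rose from 1.97 ± 0.766 to 219 ± 54.6 CPM. The collagenase MMP8 rose from 11.6 ± 3.76 to 116 ± 67.4 CPM, and ALAS2 and HBB rose to 1.68 ± 0.664 and 0.571 ± 0.164 CPM, calls that library totals ended. PECAM1 fell 2.07-fold and COL1A2 1.34-fold, the latter no longer called without ADA2 replicate 2, PBS replicate 1 or PBS replicate 3 (log2 fold changes of -0.42, -0.36 and -0.37), nor with the replicate block in DESeq2, the largest bin or the 3' end of its bins. CD6, CD79A and FCGR3B did not pass, at 1.19 ± 0.305, 16.5 ± 4.4 and 1.55 ± 0.338 CPM in ADA2. FCGR3B was called higher with the replicate block in edgeR (0.59) and DESeq2 (0.64), without PBS replicate 3 (0.87) and with the 3' end of its bins (0.69). CD6 was called higher with the largest bin (1.17), and CD79A lower under library totals (-0.53).

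Library composition differed between the groups in every library. Mitochondrially encoded mRNAs held 0.132 ± 0.00508% of gene sums in ADA2 and 0.7 ± 0.0905% in PBS, and the listed ribosomal protein mRNAs 1.31 ± 0.0844% and 2.13 ± 0.122% (SD, n = 3 each). Such shares carry no composition scaling. Under library totals the median log2 fold change of the ribosomal protein list was -0.67, near the -0.64 of all tested genes. The 10 most abundant genes of each library held 19.2 ± 0.678% in ADA2 and 14.1 ± 0.182% in PBS. They were taken per library and are not the same genes in both groups. All 3 shares separated the groups with a two-sided exact permutation p = 0.1, the smallest that 3 against 3 libraries allow, and total counts did not separate them (exact permutation p = 0.7, n = 3 each). ADA2 replicate 3 stood apart in coverage: its median log2 ratio of 5'-end to 3'-end counts was -1.68, against -1.01 to -1.08 in the other 5 libraries. Without that library 6119 genes were higher and 6318 lower. TRIM22, IL32, SERPINB2, HILPDA, MT1B, MT1X, CFB, C1S, NDUFS1, HSPA8, APOE and MT-ND4 also lie in joined features, and FCGR1A and FCGR3B have close paralogs, which makes these values less certain too.

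**Figure D4:**
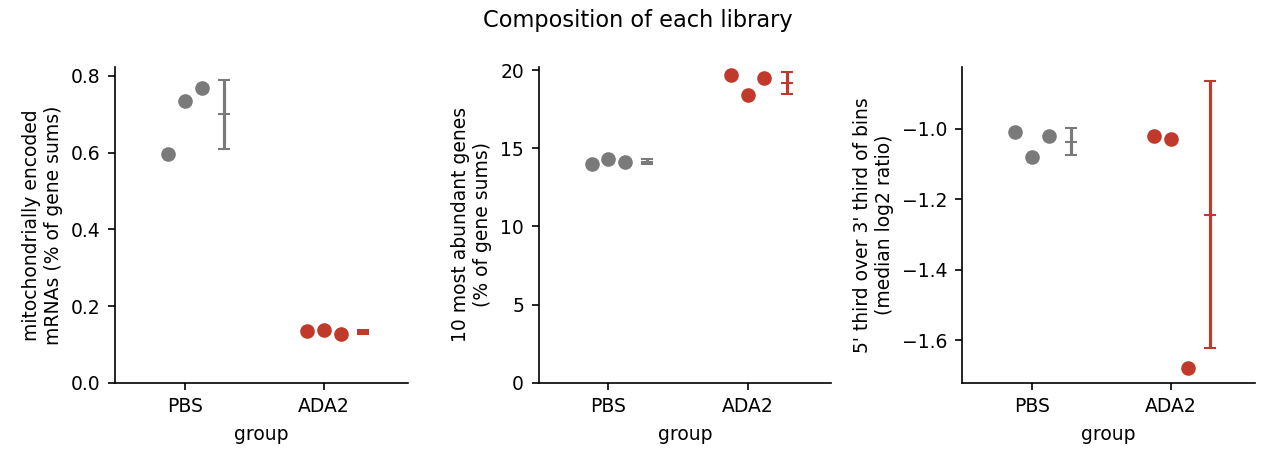
Share of mitochondrially encoded mRNAs, share of each library's own 10 most abundant genes (% of gene sums) and median log2 ratio of 5'-end to 3'-end bin counts. Points are libraries and bars mean ± SD, by group. ADA2 replicate 3 lies at -1.68 in the last panel, below the other 5 libraries.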

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

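The test of bins given to no single gene was chosen only after the data were seen. Those bins belong to features that join overlapping genes of the same strand and were left out of the report's comparisons. Of 1007 such features with enough counts, 305 were higher and 350 lower in ADA2 than in PBS (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p of 0.05). Among all genes of the main test 70.9% were called. A read counts in every bin it touches, so these bins can share reads with kept bins and are not a separate measurement.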

How the results depend on the processing

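The main counts of 5569 higher and 5860 lower genes ran from 4446 to 6000 and from 4788 to 6466 under DESeq2 size factors, both other filters, the DESeq2 Wald test, limma-voom, limma on the rlog table, the thresholds 0.01 and 0.1, and the bin choices added after seeing the data (largest bin, opposite-strand bins kept, 3' end). Library totals gave 3476 higher and 8889 lower, by construction, since no composition scaling moves the median gene to -0.64; 81.7% of the called genes kept call and direction and 220 were called the opposite way. Requiring a 2-fold change left 3661 and 3481, which counts fewer genes by construction. Leaving out 1 library gave 5160 to 6119 higher and 5355 to 6318 lower genes. The replicate block gave 5189 higher and 5514 lower genes in edgeR and 5321 and 5164 in DESeq2. Deviations of same-numbered libraries correlated at 0, -0.06 and -0.09, which gave no sign that the numbers pair the samples. These values cannot exclude a pairing, which the labels do not state. Camera called 10 lists higher and 4 lower, 0 and 0 with an estimated correlation (7 and 0 at an unadjusted p under 0.05) and 21 and 7 with fry, 10 and 4 with the replicate block, 11 and 6 with library totals (chosen after seeing the data), and 9 to 10 and 4 to 5 without 1 library; the cause of the loss was not tested. Of 2496 values of 147 named genes under alternatives, 2464 kept direction and side of the threshold, 8 lost a call, 11 gained one and 13 reversed. The reversed values belong to 5 genes not called in the report, all but FCGR3B near 0. Under library totals log2 fold changes were -0.48 for CD6, -0.53 for CD79A, -0.06 for FCGR3B and -0.58 for RPL8 (CD79A and RPL8 then called), and without a filter -0.01 for CD79A and -0.05 for RPL8. With 1 library left out they ran from -0.27 to 0.01 for APOE, -0.11 to 0.54 for CD6 (also -0.07 and -0.01), -0.14 to 0.24 for CD79A and -0.02 to 0.06 for RPL8; the cause was not tested. The share differences kept direction without mitochondrial genes in the denominator. They were -0.842 instead of -0.825 percentage points for ribosomal protein mRNAs and 4.99 instead of 5.06 for each library's own 10 most abundant genes. Depth limits genes such as ADORA1 and ADORA3, with 7 and 6 summed counts in ADA2.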

Other observations

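Families of genes that share a symbol stem were tested after the data were seen, 162 families of at least 10 genes, with camera and Benjamini-Hochberg adjustment over families. Genes of mitochondrial translation and import fell together: 33 of 49 MRPL genes (mitochondrial large ribosomal subunit) were lower and 4 higher, 22 of 29 MRPS genes lower and 3 higher, and 13 of 15 TIMM genes (inner membrane translocase) lower and 1 higher, with median log2 fold changes of -0.75, -0.83 and -1.22 (adjusted p = 0.0013, 0.0026 and 0.0041). With an estimated correlation the adjusted p were 0.8, 0.66 and 0.66. Nuclear pore genes (NUP) were lower in 16 of 21 cases, tRNA methyltransferase genes (TRMT) in 13 of 17 and small-subunit processome genes (UTP) in 9 of 10 (adjusted p = 0.016, 0.017 and 0.031, each with adjusted p = 0.66 with an estimated correlation).

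The zinc finger family ZNF, with 452 tested genes, had 217 lower and 73 higher, a median of -0.51 (camera adjusted p = 0.031; adjusted p = 0.66 with an estimated correlation). Besides chemokines and metalloproteinases, the stems that rose were IRF, with 9 of 11 higher and 1 lower, and KLF, with 10 of 14 and 1. The BCL stem had 12 of 18 higher and 0 lower, and the KDM stem (histone demethylases) 12 of 17 and 2. Genes were grouped by symbol alone, so a stem can hold genes outside the family it is named for. Camera adjusted p were 0.031, 0.047, 0.0027 and 0.044 for IRF, KLF, BCL and KDM. With an estimated correlation the adjusted p were 0.66, 0.66, 0.66 and 0.82. In all, 7 families were called higher and 13 lower, and under library totals the medians of these 4 rising families stayed above 0, at 0.8, 0.39, 0.98 and 0.06.

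The comparisons under library totals and without ADA2 replicate 3 had been planned, but their use as tests here, with their bounds, and the other tests that follow were chosen after the results were seen. Most tested genes differed between the groups, 11429 in the real grouping. The other 9 of 10 splits of the 6 libraries called at most 0 genes at adjusted p under 0.05 in edgeR and at most 147 at an unadjusted p under 0.05. Each of them mixed ADA2 and PBS libraries on both sides. The difference between ADA2 and PBS thus widened the spread within each side and left little room for calls. Their counts therefore do not measure what chance would give. The 10 splits, of which 1 reached the real count, are also too few for a share under 0.05. Under library totals 81.7% of called genes kept call and direction. This share cannot decide on composition scaling set by a few abundant genes, because library totals lower the fold change of every gene. Called falls thus had little room to be lost, while rises went from 5569 to 3476 and 220 genes were called the opposite way. The 3476 rises were called against that shift, so the scaling alone does not account for them. The library with more counts at the 3' end, ADA2 replicate 3, does not carry the calls, since 97.8% were kept without it. The contrast tested the difference between ADA2 and PBS libraries, and whether the ADA2 protein itself causes that difference stays open.

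The rise of NF-kB cytokines and chemokines could come from the ADA2 protein or from a microbial ligand carried in its preparation. All 27 tested members of the NF-kB list rose, which both would give, and with no library of inactive or mock-purified protein the 2 cannot be told apart here. The median ADA2 level over 40 listed markers of T, NK, B, red cells, neutrophils and platelets was 0.482 CPM. List medians in ADA2 were 2.62 CPM for NK cells (0.2 in PBS), 1.03 for neutrophils (1.06) and 0.757 for B cells (0.298). Those of platelets, red cells and T cells were 0.403 (0.981), 0.365 (0.246) and 0.324 CPM (0.132). Low medians cannot exclude a small share of any of these cells, and 5 markers reached 10 CPM. Camera called the NK list higher (Benjamini-Hochberg adjusted p = 0.0096, and 0.25 with an estimated correlation). Its adjusted p was 0.085 without ADA2 replicate 3 and 0.054 without PBS replicate 1. PPBP of the platelet list rose to 219 CPM, while PF4, chosen after its value was seen, reached 0.403 CPM. For dendritic cells in the ADA2 libraries, 4 of 10 listed markers rose, among them CCR7 to 711 CPM, and 5 fell from low levels, so such cells, or a shift of the macrophages, cannot be told apart here.

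Mitochondrially encoded mRNAs fell, and dilution by newly abundant mRNAs might lower them along with every other gene. Under library totals their median lay at -2.71 relative to the median gene, a gap that the choice of scaling leaves nearly unchanged. Dilution would lower all genes alike, so it alone does not account for the gap. The 3'-shifted library is not the source either, since the median without ADA2 replicate 3 was -2.59. A difference in capture of these transcripts by polyA selection was not tested and stays open beside an effect of the treatment.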
